A study of Mus musculus with 2 samples.

How the data were processed

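The deposited values are raw UMI counts per gene and barcode, which per the labels were made with Cell Ranger against the mm10 mouse genome. The version of Cell Ranger, its settings and the rule by which barcodes were called as cells are not given in the sources used here. The lowest barcode total, 4212 UMIs in Control and 3514 in NAPH, lay near 0.1 of the 99th percentile of each library (4112 and 3408). Symbols and positions came from GENCODE vM21 (GRCm38), in which 28339 of 28692 gene IDs were found. Near copies exist of H2-Q6 and H2-Q7, Cyp2a5, Chil4, Lyz1, Acot1, Ces1d, Bex2 and Bex4, and how reads were split among such copies is not given in the sources used here. Neither library held UMIs of 4 Y-linked genes, and Xist had 23420 UMIs in Control and 21047 in NAPH.

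Barcodes with fewer than 500 genes, fewer than 1000 UMIs or more than 20% mitochondrial UMIs were left out, 0 in Control and 4 in NAPH. Doublets were scored with Scrublet within each library. The automatic threshold was kept where it called between 0.5% and 15% of cells, and otherwise cells were removed at an expected rate of 0.8% per 1000 barcodes. It called 0.546% in Control, where 18 cells were removed, and 0.299% in NAPH, where the expected rate of 2.94% was used and 108 cells were removed. The remaining 6853 cells were clustered jointly in scanpy 1.11.5 on Python 3.11.15, without batch correction. Counts per cell were scaled and log-transformed, 2000 variable genes, 30 principal components and 15 neighbours were used, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) was run at resolution 1. A cluster took the name of the class, out of 20 with marker lists, that had the most markers among its top 50 genes, where this was at least 3 and no other class had more among the top 10. Names carry the ending "-like" because they rest on RNA markers alone.

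UMIs were summed per class and library where both libraries held at least 50 cells of the class, which gave 6 classes. Ratios are NAPH over Control with exact conditional Poisson intervals. Where a gene had no UMIs in a library, the ratio is a lower bound against 3 counts summed over the class. A gene was taken to be within reach of free RNA when, in the library where it was higher, its level in a class was below 0.2 times that in another class. Unnamed clusters and classes with fewer than 50 cells in that library did not count as another class. Shares have exact binomial intervals. Scaling by edgeR 4.0.16 (TMM, R 4.3.3) moved the ratios in club-like, goblet-like and ciliated-like cells by 0.80, 0.51 and 0.32 on the log2 scale, close to the median of all genes in these classes.

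The genes named in the text follow a rule. In the 3 classes with the most cells in the smaller library, AT2-like, ciliated-like and dendritic-like cells, the 10 highest and 10 lowest ratios are named, and in the other classes 3 of each. A named gene had at least 100 CPM in a library and at least 50 UMIs. Ribosomal, mitochondrial, haemoglobin, sex-linked and unnamed predicted genes, markers of another class and genes within reach of free RNA were passed over. Up to 2 highest and 2 lowest members of a list, with at least 30 UMIs, and the genes Scgb1a1, Scgb3a2, Cyp2f2, Foxj1, Sftpc, Krt5, Mki67 and Top2a were also named, with those within reach of free RNA given only in part. Some genes that this rule names are not reported here. For AT2-like and club-like cells every list is reported. Which lists to describe in the other classes was decided after their values were seen.

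For 24 lists, members with at least 10 UMIs were used, with 5 members as the minimum. The list median of log2 ratios was placed among 10000 random lists matched on expression in 20 bins, and the percentile is given. A percentile ranks genes within 1 pair of libraries and is not a test between the conditions. The lists cover club secretory products, xenobiotic metabolism, NRF2, p53, Wnt and YAP targets, S phase, G2 and M phase, interferon response, MHC class I and class II, inflammatory mediators, type 2 response and immediate early genes. They also cover heat shock, unfolded protein response, transitional epithelial genes, Notch pathway, cholesterol and fatty acid synthesis, glycolysis and hypoxia, surfactant and lamellar body, ciliogenesis regulators and extracellular matrix. The classes, markers, lists, thresholds, naming rule and the first set of alternative settings were chosen before the data were examined.

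The ratio and list steps were tried on Poisson counts with known ratios, drawn from the summed levels of each class. Clustering, naming, doublets, free RNA and differences between cells or animals were not simulated. The rates below therefore hold for counting error only. In AT2-like cells a true ratio of 2 was recovered as 1.97 at the median, the interval covered it for 98% of genes and left out 1 for 88%. The interval left out 1 for 4.07% of genes with no difference. For a true ratio of 0.5 the interval left out 1 for 60% of genes in club-like and 72% in ciliated-like cells. A list of 20 with 10 members raised stood at the 100th percentile in each class. Of 100 lists with no difference, 10 lay outside the middle 95% in AT2-like cells, 4 in club-like, 2 in ciliated-like, 6 in dendritic-like, 3 in goblet-like and 3 in macrophage-like cells.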

Results

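Cells of adult C57BL/6 mouse lung were sorted by flow cytometry for Epcam, an adhesion protein of epithelial cells, and their RNA was counted with a droplet-based single-cell 3' kit. There was 1 Control library and 1 library made after an injury that the labels abbreviate as NAPH. The dose, the time after injury and the number of animals behind each library were not given in the sources used here. The Control library held 3298 barcodes and 41699755 unique molecular identifiers (UMIs), with a median of 8303.5 UMIs and 2052 genes per barcode. The NAPH library held 3685 barcodes and 38497783 UMIs, with medians of 9417 UMIs and 2329 genes. After filtering and removal of doublets, 3280 Control and 3573 NAPH cells remained. With 1 library per group there is no replicate check, so no test between the groups was made and each difference is between these libraries. Ranges in parentheses are exact 95% intervals, binomial for shares and Poisson for count ratios, and cover counting error only.

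The question posed by the series title is how the airway epithelium differed after the injury. Club-like cells, the Scgb1a1-rich secretory cells of the airway, made up 19.5% (18.1 to 20.8) of Control cells, 638 in number. They made up 4.28% (3.64 to 5.0) of NAPH cells, 153 in number, a share 0.220 times as large (0.183 to 0.263). Goblet-like cells, the mucin-producing secretory cells, made up 4.12% (3.46 to 4.85) and 2.46% (1.98 to 3.03). Club-like and goblet-like cells together made up 23.6% of Control and 6.75% of NAPH cells, a ratio of 0.286 (0.247 to 0.331). By cluster, the Control and NAPH cells numbered 473 and 13 in cluster 5, 150 and 2 in cluster 11 and 135 and 15 in cluster 12, but 15 and 138 in cluster 10 and 0 and 73 in cluster 15. Ciliated-like cells made up 6.52% (5.70 to 7.42) of Control and 5.71% (4.97 to 6.52) of NAPH cells, and the interval of their ratio, 0.719 to 1.07, includes 1. Basal-like cells, the stem cells of the large airway, numbered 11 (0.335%) and 48 (1.34%), a ratio of 4.01 (2.05 to 8.55). Neuroendocrine-like cells numbered 7 (0.213%) and 21 (0.588%), a ratio of 2.75 (1.13 to 7.67).

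Because many genes, class markers among them, differed between the libraries, the cells were also clustered without 5458 such genes. These differed at least 1.5 times on summed UMIs within AT2-like cells, ciliated-like cells, pooled club-like and goblet-like cells, or pooled dendritic-like and macrophage-like cells. The clusters were still named with all genes, so differing markers could still affect the names. The ratio of club-like shares was then 0.259, that of club-like and goblet-like cells together 0.271, that of ciliated-like cells 0.875 and that of basal-like cells 4.74. These are shares of Epcam-sorted cells, and the lowest barcode held 4212 UMIs in Control and 3514 in NAPH. Of the NAPH cells, 121 lay below the Control minimum, among them 16 ciliated-like, 5 basal-like and 1 neuroendocrine-like cell. The boundary between club-like and goblet-like cells was not stable. With only cells of at least 4212 UMIs the club-like ratio was 0.0245 and the goblet-like ratio 1.26, while the ratio of both classes together was 0.267. The size of the joint ratio also depended on the settings, at 0.0351 with resolution 0.5 and 0.0243 with the stricter cell filter. In these settings, as with the UMI minimum, clusters were formed and named anew, so cells could change class rather than be lost. By the highest marker score per cell the basal-like ratio was 1.70.

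AT2-like cells, the surfactant-producing cells of the alveolus, made up 53.8% (52.1 to 55.5) of Control and 43.4% (41.8 to 45.1) of NAPH cells. No direction can be given for this share. Unnamed clusters 3 and 8 held Sftpc, the surfactant protein C gene, at 187270 and 159125 CPM in the NAPH library, against 224829 in AT2-like cells. The top genes of cluster 3 began with Lrg1, Il33 and Pmvk. Those of cluster 8 included Sprr1a, Areg, Hbegf, Sfn, Krt8 and Krt7, several of them on the transitional epithelial list. Joined with these clusters, AT2-like cells were 54.8% of Control and 69.7% of NAPH cells, and clustering without the differing genes gave a ratio of 1.22 for AT2-like cells alone. Unnamed clusters in all held 3.14% of Control and 28.9% of NAPH cells. By cluster, these shares were 0.0915% and 18.1% for cluster 3, 0.915% and 8.17% for cluster 8, and 1.34% and 0.868% for cluster 14. For cluster 16 they were 0.488% and 1.23%, and for cluster 21 they were 0.305% and 0.504%.

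Non-epithelial cells that passed the Epcam sort made up 12.4% (11.3 to 13.6) of Control and 13.3% (12.2 to 14.4) of NAPH cells. Dendritic-like cells were 7.32% and 5.43% of the libraries, and macrophage-like or monocyte-like cells were 5.09% and 6.88%. Neither direction was stable, with a dendritic-like ratio of 5.48 when each library was clustered on its own and a macrophage-like ratio of 0.431 at resolution 0.5. The ratio of all non-epithelial cells was 3.27 and 0.697 in these settings. No T-like or NK-like cell was found among 3280 Control cells, which allows a share of up to 0.112%, and 22 (0.616%) were found in NAPH. By the highest marker score per cell there were 10 in Control and 31 in NAPH. Of the 22, 10 had fewer UMIs than any Control barcode. Their cluster had 13 T or NK markers among its top 50 genes, but was led by the B cell markers Igkc and Ighm. It may therefore hold B-like cells as well. Fibroblast-like cells numbered 1 and 12.

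**Figure D1:**
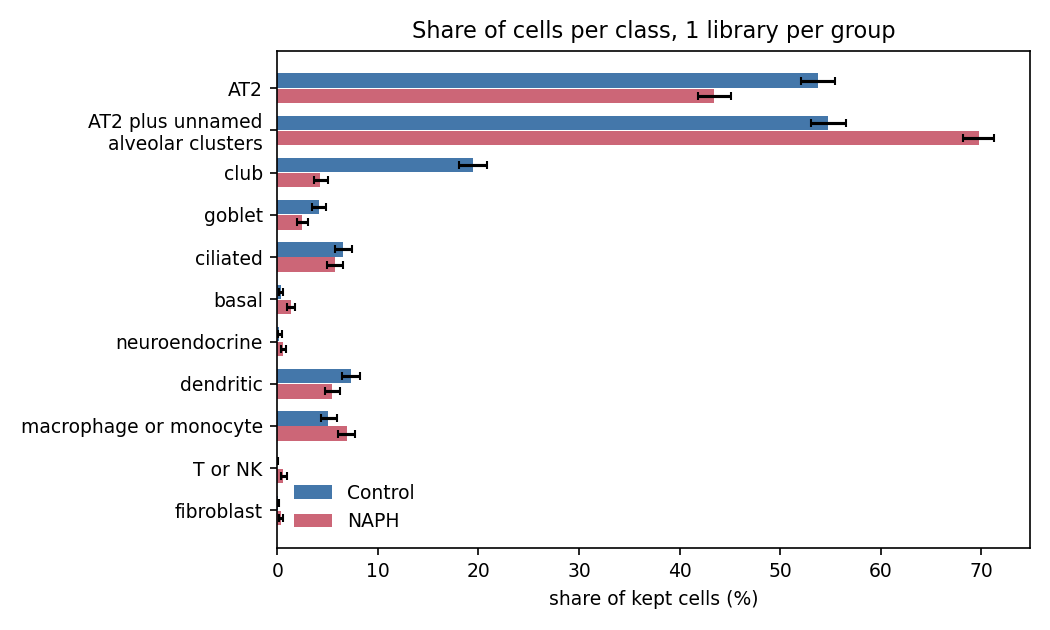
Share of kept cells (%, horizontal axis) in each class for the Control and NAPH libraries, 1 library each; error bars are exact 95% binomial intervals. Club-like cells were 19.5% of Control and 4.28% of NAPH cells, and AT2-like cells were 53.8% and 43.4%, or 54.8% and 69.7% with the unnamed alveolar clusters.

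Within a class, levels are CPM, the usual scaling of summed UMIs to a common total per class and library. Scgb1a1, which encodes the main secretory protein of club cells, took 61.7% of all club-like UMIs in Control and 33.9% in NAPH, and CPM of other genes go up where its share is lower. The median log2 ratio of all genes, NAPH over Control, was 0.77 in club-like, 0.51 in goblet-like and 0.34 in ciliated-like cells. It was 0.06 in AT2-like and -0.01 in dendritic-like cells. Ratios in club-like, goblet-like and ciliated-like cells are given relative to that median, and those in AT2-like and dendritic-like cells as plain CPM ratios. Counts of list members higher or lower follow the same scale as the ratios of their class.

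In AT2-like cells the highest ratio among the genes named by the rule was that of Lrg1, which encodes a secreted glycoprotein of the acute phase, at 189.6 CPM in Control and 1791 in NAPH (9.44 times, 9.07 to 9.84). Scd1, the stearoyl-CoA desaturase gene, stood at 2775 and 9998 CPM (3.60 times, 3.56 to 3.64), and Lcn2, which encodes an iron-scavenging lipocalin, at 830.5 and 2536 CPM (3.05 times, 2.99 to 3.12). The other genes named as higher were Itih4 (4.11), Pmvk of the mevalonate pathway (4.0), the alarmin gene Il33 (3.20), the protease inhibitor gene Slpi (3.15), Ptgs1 (3.09), Gclc of glutathione synthesis (2.55) and Cd302 (2.42). The lowest ratios were those of Bex2 (0.480, 0.461 to 0.50) and the lysozyme gene Lyz1 (0.530, 0.521 to 0.538), both among the markers that named the class. Acot1 (0.552), the carboxylesterase gene Ces1d (0.566), Bex4 (0.582), Stmn1 (0.608), Hspb1 (0.610), Hmgb2 (0.624), Anxa5 (0.667) and Tst (0.677) followed. Sftpc itself stood at 242576 and 224829 CPM, a ratio of 0.927 (0.925 to 0.928). Different clusters held most of the class, clusters 0 and 4 in Control and clusters 1 and 2 in NAPH. Within clusters Lrg1 differed less, at 145.4 and 381.8 CPM in cluster 0, 57.6 and 126.3 in cluster 4, 678.8 and 1006 in cluster 1 and 1539 and 2907 in cluster 2. Lcn2 likewise stood at 807.6 and 1272 CPM in cluster 0, 590.1 and 901.2 in cluster 4, 1594 and 1987 in cluster 1 and 1655 and 3429 in cluster 2. With clusters 3 and 8 joined, Lrg1 was 11.6 times and Pmvk 6.10 times higher, and no named gene turned direction.

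**Figure D2:**
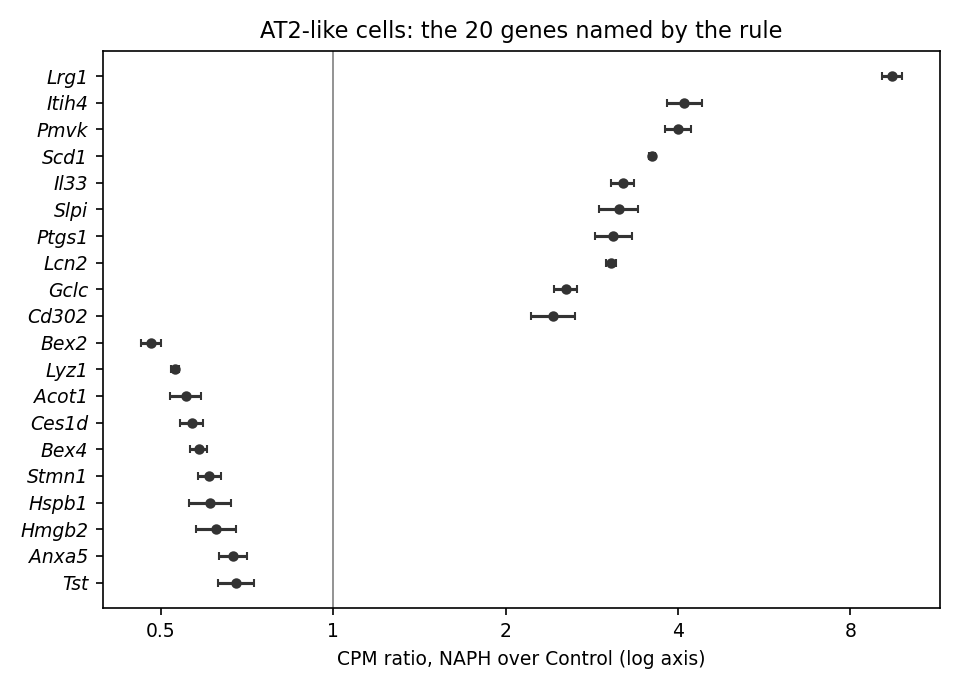
CPM ratio, NAPH over Control, on a log axis for the 20 genes named by rule in AT2-like cells, 1 library per group; bars are exact 95% Poisson intervals and cover counting error only. Lrg1 lies at 9.44 and Bex2 at 0.480.

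Some lipid synthesis genes were higher in the AT2-like cells of the NAPH library. The cholesterol synthesis list had a median log2 ratio 0.38 above that of all genes, at the 100th percentile of random lists matched on expression, with 5 of 19 members at least 1.5 times higher, 0 lower and 14 between. Among the higher were Fdps (1.81, 1.72 to 1.91) and Mvd (1.61, 1.38 to 1.87), while Insig1 stood at 0.862 (0.798 to 0.931). The cholesterol synthesis list was not particular to AT2-like cells, since its median in dendritic-like cells lay 0.37 above all genes. In the fatty acid synthesis list, 0.33 above all genes, 5 of 13 members were at least 1.5 times higher, 1 lower and 7 between, with Fasn at 1.80 (1.75 to 1.85) and Me1 at 1.60 (1.49 to 1.71). The surfactant and lamellar body list was 0.04 above all genes, with 0 of 15 members at least 1.5 times higher and 1 lower. Its members Sftpd (1.36), Lpcat1 (1.23) and Etv5 (0.767) differed in direction.

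The inflammatory mediators list in AT2-like cells was 0.36 above all genes (percentile 100), with 7 of 19 members at least 1.5 times higher and 1 lower. The serum amyloid gene Saa3 had 3 Control and 70 NAPH UMIs (22.4 times, 7.36 to 111). Il6 had 0 and 36 UMIs, at least 11.5 times higher against a floor of 3 counts, whereas Csf2 stood at 0.794 (0.666 to 0.946). The type 2 response list was 0.59 above all genes (percentile 100), with 6 of 9 members higher, led by the anion exchanger gene Slc26a4 (4.94, 3.96 to 6.23) and Ptgs1. It was 0.09 above with the stricter cell filter. The unfolded protein response list was 0.29 above, with 3 of 21 members higher, among them Chac1 (6.48, 3.06 to 15.8) and Atf5 (1.65, 1.37 to 1.99). The MHC class I list was also 0.29 above, with 3 of 13 higher, including H2-Q6 (1.97, 1.42 to 2.77) and H2-Q7 (1.67, 1.35 to 2.06).

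The xenobiotic metabolism list in AT2-like cells had a median of -0.67 relative to all genes (percentile 0), with 14 of 28 members at least 1.5 times lower, 2 higher and 12 between. Free RNA from other cells could give 16 of these members, and without them the median was -0.23. Wnt targets and the Notch pathway each lay at -0.30 (percentiles 1.33 and 2.10). Smaller medians were those of p53 targets at 0.15 (97.0), led by Sesn2 at 1.99 (1.59 to 2.51), NRF2 targets at 0.13 (97.1), immediate early genes at 0.13 (97.7) and glycolysis and hypoxia at 0.07 (80.0). Club secretory products lay at 0.24 (99.7), with 6 of 16 members higher, 6 lower and 15 that free RNA could give. The medians of ciliogenesis regulators (0.22, 90.5), MHC class II (0.03, 60.7, all 9 members within reach of free RNA), interferon response (0.01, 59.2) and heat shock (-0.02, 41.2) lay within the middle 95% of random lists. The same held for G2 and M phase (-0.06, 27.9), YAP targets (-0.08, 22.8) and extracellular matrix (-0.06, 22.4). The S phase list at -0.19 (1.86) changed sign with thinned cells (0.01), and transitional epithelial genes at -0.14 (1.12) stood at 0.69 with clusters 3 and 8 joined.

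Club-like cells were compared between 638 Control and 153 NAPH cells, which lay mostly in different clusters, clusters 5 and 11 in Control and cluster 10 in NAPH. The genes named as highest were Spink5, a serine protease inhibitor gene, at 1.63 and 216.4 CPM (78.0 times relative to all genes, 53.7 to 117), the uroplakin gene Upk3a at 6.05 and 315.6 CPM (30.5 times, 25 to 37.6), and the acidic chitinase gene Chia1 at 35.1 and 1375 CPM (22.9 times, 21 to 25). Genes named as lower were the cytochrome P450 gene Cyp4b1 (0.142, 0.126 to 0.158) and the paraoxonase gene Pon1 (0.151, 0.132 to 0.173). With goblet-like cells joined to the class, the plain CPM ratio of Spink5 was 55.6 in place of 133. Much of these ratios lies between clusters, since within cluster 10, with 15 Control and 138 NAPH cells, plain CPM ratios were 4.93 (2.92 to 9.08) for Spink5, 8.42 (4.79 to 16.3) for Upk3a and 2.38 (2.05 to 2.77) for Chia1. Among the markers that named the class, Scgb1a1 stood at 617397 and 339176 CPM (0.322 relative to all genes) and Cyp2f2, a cytochrome P450 gene of club cells, at 5896 and 3181 CPM (0.316, 0.309 to 0.323). Scgb3a2, another secretoglobin gene, stood at 12010 and 33317 CPM (1.62, 1.61 to 1.64).

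Xenobiotic metabolism was the list with the lowest median in club-like cells, at -1.25 relative to all genes (percentile 0), with 20 of 31 members at least 1.5 times lower and 0 higher. On plain CPM, 14 members were lower and 7 higher. Club secretory products lay at -0.40 (0.01), with 8 of 16 members lower and 5 higher, and at 1.22 when clustered without the differing genes. On plain CPM the tally was the reverse, with 5 members lower and 8 higher. The type 2 response list lay at 1.97 (100), with 7 of 11 members higher, led by Chia1 and by Retnla, a resistin-like cytokine gene, at 375.3 and 10098 CPM (15.8 times, 15.3 to 16.2). Within cluster 10 the plain CPM ratio of Retnla was 70.6 (52.5 to 97.1). Free RNA could give 7 of these 11. The transitional epithelial list lay at 1.33 (100), with 17 of 23 members higher and 0 lower, including the small heat shock gene Cryab (3.50, 3.14 to 3.91). S100a6 (6.65) and Areg (5.24) belong to this list too, but free RNA could give both. Within cluster 10 both were lower in NAPH, S100a6 at a CPM ratio of 0.428 (0.383 to 0.481) and Areg at 97.4 and 21.1 CPM. In the extracellular matrix list, 1.21 above all genes (100), 10 of 14 members were higher and 0 lower, among them Thbs1 (9.31, 6.04 to 14.7). Inflammatory mediators lay at 0.71 (100), with Ccl20 at 31.8 times (18.6 to 58.4) on 15 and 133 UMIs.

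Further lists with high medians in club-like cells included MHC class II (0.96, 100), led by Cd74 (5.12), and surfactant and lamellar body (0.92, 100), whose highest-level gene Sftpc stood at 1.52. Free RNA could give 7 of 7 and 8 of 14 of their members. Fatty acid synthesis lay at 0.67 (100, 8 of 14 within reach of free RNA), G2 and M phase at 0.69 (100), ciliogenesis regulators at 0.54 (98.9, but -0.11 when clustered without the differing genes) and interferon response at 0.47 (99.6). Cholesterol synthesis (0.36, 99.7), S phase (0.30, 99.3), p53 targets (0.29, 98.2), Notch pathway (0.26, 93.8), glycolysis (0.20, 95.2), MHC class I (0.18, 87.4), unfolded protein response (0.14, 87.1) and Wnt targets (0.14, 88.1) lay closer to all genes. So did NRF2 targets (-0.02, 33.2), although their member Gclc stood at 3.26 (2.93 to 3.63). Below all genes lay YAP targets (-0.34, 3.35), heat shock (-0.24, 2.41), with Hspb1 at 0.339, and immediate early genes (-0.19, 2.23), whose members Socs3 (4.36) and Cyr61 (5.61) went the other way. With members of at least 30 UMIs the G2 and M phase median was 0.04, and with thinned cells the interferon median was 0.06 and that of MHC class I -0.15.

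**Figure D3:**
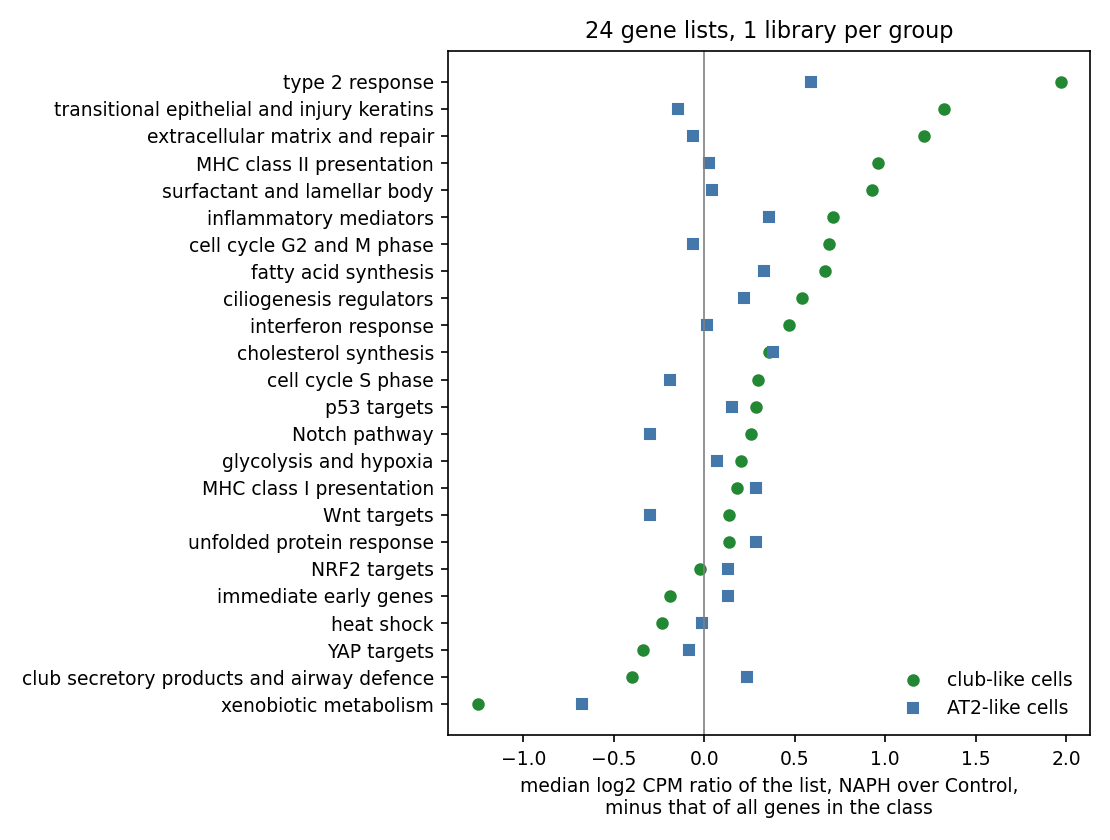
Median log2 CPM ratio of each of 24 gene lists, NAPH over Control, minus that of all genes in the class (horizontal axis), for club-like cells (circles) and AT2-like cells (squares), 1 library per group and no error bars. Xenobiotic metabolism is the lowest list in both classes, at -1.25 and -0.67, and type 2 response the highest, at 1.97 and 0.59. In AT2-like cells these were -0.23 without members that free RNA could give and 0.09 with the stricter cell filter.

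Goblet-like cells were compared between 135 Control cells, all in cluster 12, and 88 NAPH cells, of which 73 lay in cluster 15. Upk3a had 0 UMIs in Control and 601 in NAPH, at least 223 times higher relative to all genes against a floor of 3 counts. The chitinase-like gene Chil4 was 23.1 times higher (14.2 to 40.2), Lrg1 13.3 times (10.3 to 17.3), Lcn2 13 times (11.1 to 15.3) and Retnla 12.7 times (12.3 to 13.1). Lrg1 stood at 381.7 CPM in NAPH goblet-like cells, against 1791 in AT2-like cells and 3451 in unnamed cluster 3. In macrophage-like cluster 13 Lrg1 was higher in NAPH too, at 11.4 and 327.5 CPM. Free RNA therefore stays open for Lrg1 in goblet-like cells. The genes named as lowest were Cyp4b1 (0.202, 0.175 to 0.232), Fgfbp1 (0.298, 0.234 to 0.378) and the class marker Reg3g, an antimicrobial lectin gene (0.301, 0.291 to 0.312). Reg3g stood at 0.924 as a plain CPM ratio, in place of 0.428, when the cells were clustered without the differing genes. The S phase list lay 1.49 above all genes (percentile 100), with 26 of 32 members higher and 0 lower, and the G2 and M phase list 0.72 above (100), with 14 of 23 higher and 1 lower. Counts behind these lists were low, with 3 and 29 UMIs of Mcm2, 0 and 31 of Hells, and 1 and 15 of Top2a. Clustered without the differing genes, their medians were 0.82 and 0.07. Type 2 response lay at 1.51 (100), with 9 of 13 members higher and 0 lower. Xenobiotic metabolism lay at -0.73 (0), with 17 of 29 members lower and 1 higher, including Cyp2a5 (0.151, 0.116 to 0.193). Club secretory products lay at -0.42 (0.05), with 4 of 16 members higher and 7 lower, and on plain CPM 6 higher and 6 lower. The goblet marker Bpifb1 stood at 0.320 (0.310 to 0.331), while Lcn2 and Retnla, given above as higher, belong to the same list. The club cell genes stood at 0.406 for Scgb1a1, 1.15 for Scgb3a2 and 0.425 for Cyp2f2.

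Ciliated-like cells fell into the same 2 clusters in both libraries, cluster 7 with 184 Control and 183 NAPH cells and cluster 19 with 30 and 21. Median UMIs per cell were 5468.5 and 8067.5, genes 2353.5 and 3064.5, and the mitochondrial share 3.75% and 5.15%. Cd177, which encodes a surface glycoprotein known from neutrophils, was the gene with the highest ratio among those named by the rule, at 6.33 and 212.5 CPM (26.6 times relative to all genes, 14.7 to 53.6). The calcium-binding protein gene S100a6 stood at 604.0 and 6211 CPM (8.14 times, 7.64 to 8.68), and the growth factor gene Areg, which encodes amphiregulin, at 46.6 and 462.9 CPM (7.86 times, 6.25 to 9.99). The ghrelin gene Ghrl (6.27, 5.22 to 7.60), the clusterin gene Clu (4.12, 3.41 to 5.02), Adam8 (4.02), Lgals3 (3.53), the class marker AU040972 (3.26), Arl4c (3.25) and Muc4 (3.24) were also higher. Lower were Lat (0.280, 0.212 to 0.367), the transferrin gene Trf (0.323, 0.259 to 0.401), Mgst1 (0.349, 0.315 to 0.387) and Pcp4l1 (0.352, 0.320 to 0.386). Tstd1 (0.400), Cdkn1c (0.426), Kcnq1ot1 (0.427), Nol7 (0.507), Chchd10 (0.508) and Atf4 (0.510) completed the genes named as lower.

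Scgb1a1 stood at 151934 CPM in Control and 9067 CPM in NAPH ciliated-like cells. Much of this difference lay in a few Control cells, while in cluster 7 alone Scgb1a1 stood at 21697.7 and 8405 CPM. Without 17 Control ciliated-like cells of high doublet score, and with classes unchanged, the Control level was 47697 CPM. When doublets were removed at the expected rate in both libraries, these 17 cells among them, the cells were also clustered and named anew. The CPM ratio of Scgb1a1 was then 0.282 in place of 0.0597. The ratio of Trf was 3.88 in place of 0.408 and that of Mgst1 0.901 in place of 0.441. Changed class membership can add to these moves. The ratio of Cyp2f2 was 1.18 in place of 0.700, and that of Scgb3a2, which free RNA could give, 5.27 in place of 0.421.

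**Figure D4:**
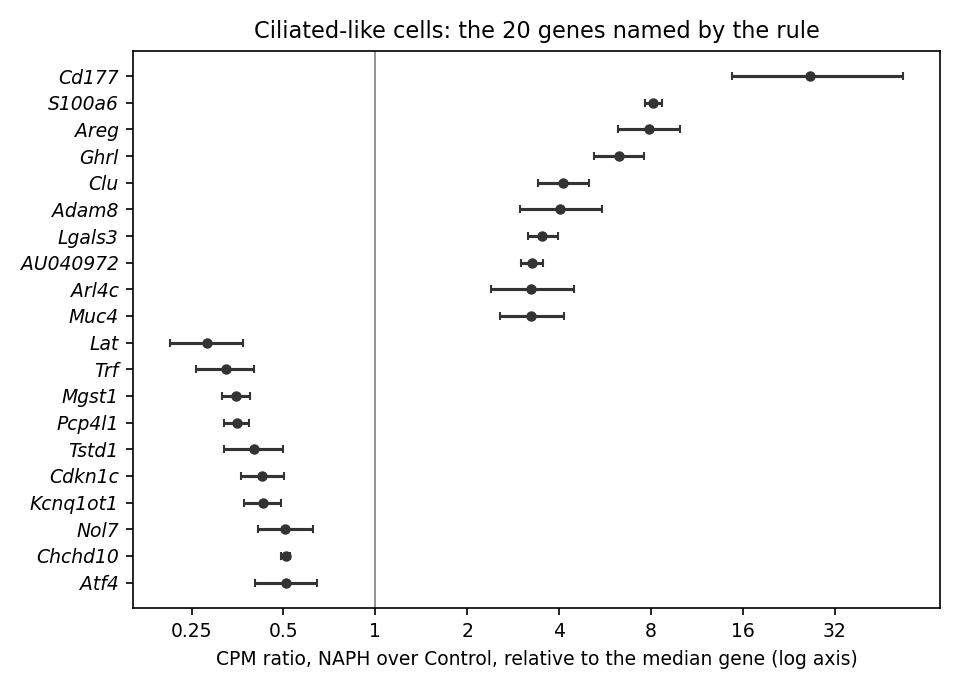
CPM ratio, NAPH over Control, relative to the median gene, on a log axis for the 20 genes named by rule in ciliated-like cells, 1 library per group; bars are exact 95% Poisson intervals and cover counting error only. Cd177 lies at 26.6 and Lat at 0.280, and the low values of Trf and Mgst1 were lost when doublets were removed at the expected rate and the cells clustered anew.

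The transitional epithelial list lay 0.97 above all genes in ciliated-like cells (percentile 100), with 15 of 22 members higher and 1 lower. Members with few counts included the growth factor gene Hbegf, with 3 and 65 UMIs (15.1 times, 4.93 to 75), and the urokinase receptor gene Plaur, with 1 and 32 (22.3 times, 3.72 to 906). The extracellular matrix list lay at 0.70 (100), with 8 of 13 members higher and 1 lower, among them Itgb6 (3.75, 1.43 to 12.5). G2 and M phase genes lay at 0.58 (100), with 17 of 35 higher and 1 lower, including Kif23 (6.72, 2.08 to 34.5) and Cenpa (6.61, 2.38 to 25.5), and at 0.18 with thinned cells. Cholesterol synthesis also lay at 0.58 (100), with 9 of 19 higher and 0 lower, including Nsdhl (3.18, 1.38 to 8.53) and Lss (2.47, 1.15 to 5.89). Interferon response lay at 0.49 (99.8), with 8 of 18 higher, led by Ifitm3 (2.93, 2.60 to 3.31), and at 0.11 with thinned cells. Immediate early genes lay at 0.39 (99.9), with Cyr61 on 2 and 45 UMIs (15.6 times, 4.09 to 133). Ciliogenesis regulators lay at 0.16 (90.2), with 2 of 14 higher and 0 lower, Ccno at 1.70 (1.33 to 2.19) and the master regulator gene Foxj1 at 840.7 and 1238 CPM (1.17, 1.09 to 1.24). Xenobiotic metabolism lay at -0.51 (0), with 11 of 27 lower, and club secretory products at -0.45 (0.05), with 12 of 16 members within reach of free RNA. With doublets removed at the expected rate these medians were 0.04 and 1.68.

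Dendritic-like cells, the antigen-presenting cells that passed the sort, lay mainly in cluster 6 in both libraries. The genes named as higher ran from S100a4 (1.97, 1.71 to 2.28) and Apol7c (1.96, 1.53 to 2.51) over the growth factor gene Tgfb1 (1.88), Cdkn1a (1.83), Picalm (1.82) and Adam8 (1.80) to the chemokine genes Ccl17 (1.75, 1.68 to 1.83) and Ccl22 (1.65, 1.53 to 1.79), Lgals1 (1.62) and Il4i1 (1.58). Ccl17 and Ccl22 are class markers. With Apol7c, Il4i1 and S100a4 they are also among the top genes of cluster 18, which held 20 Control and 39 NAPH cells and so a larger part of the class in NAPH. The genes named as lower were led by the interferon-induced gene Ifi27l2a (0.235, 0.186 to 0.294), Ccnd2 (0.392, 0.316 to 0.484) and Egr1 (0.425, 0.336 to 0.535). Mt2 (0.464), Phlda1 (0.473), Ryr1 (0.512), Myo1f (0.521), Pglyrp1 (0.530), Tlr3 (0.533) and Grap (0.536) followed.

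The proliferation genes Mki67 and Top2a were scarce in the named epithelial classes, and cells rich in them formed the unnamed cluster 16, with 16 Control and 44 NAPH cells. Unnamed clusters 14 and 21, whose cells mostly joined dendritic-like and macrophage-like cells when clustered without the differing genes, were rich in them too. In cluster 16 Top2a stood at 441.7 and 325.4 CPM, Mki67 at 142.5 and 168.5, Sftpc at 144980 and 85967.6 and Scgb1a1 at 12506 and 56350.2. AT2-like cells had 56 and 41 UMIs of Mki67 (ratio 0.703, 0.458 to 1.07) and 6 and 11 of Top2a, and club-like cells had 18 and 5 of Mki67 and 12 and 8 of Top2a. Goblet-like cells had 7 and 18 UMIs of Mki67. Dendritic-like cells had 16 and 11 of Mki67 and 41 and 13 of Top2a (0.361, 0.178 to 0.688), without cluster 14, where Top2a stood at 522.0 and 365.1 CPM. In ciliated-like cells Top2a had 20 and 58 UMIs (2.02 relative to all genes, 1.19 to 3.54) and Mki67 had 7 and 12. The basal keratin gene Krt5 had at most 5 UMIs in either library in each of the compared classes. Every AT2-like and dendritic-like cell held Scgb1a1 UMIs, at 13131 and 3312 CPM in AT2-like and 12653.5 and 2401 CPM in dendritic-like cells of Control and NAPH, so free RNA of this gene was lower in the NAPH library. By annotation of build GRCm38 the protein-coding genes named here include Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958, minus strand), Cyp2f2 (ENSMUSG00000052974, chromosome 7, 27119909 to 27133660, plus strand) and Scgb3a2 (ENSMUSG00000038791, chromosome 18, 43764289 to 43767399, plus strand). For the alveolar class they include Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081, minus strand), Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001, minus strand) and Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, minus strand). Of the genes with high ratios in airway classes, the annotation lists Upk3a (ENSMUSG00000022435, chromosome 15, 85017141 to 85022547, plus strand), Spink5 (ENSMUSG00000055561, chromosome 18, 43963235 to 44022501, plus strand) and Cd177 (ENSMUSG00000052212, chromosome 7, 24743983 to 24760311, minus strand). The regulator gene of ciliated cells is Foxj1 (ENSMUSG00000034227, chromosome 11, 116330704 to 116335399, minus strand).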

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

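Of the tests in this part, the 5 on club-like and ciliated-like cells were chosen only after their results were seen, and the 2 on AT2-like cells were written before.

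Cluster 3, which no marker list named, held 18.1% of NAPH and 0.0915% of Control cells. Cluster 8, also unnamed, held 8.17% of NAPH and 0.915% of Control cells. Cluster 16, also unnamed, held 1.23% of NAPH and 0.488% of Control cells. These clusters stand out because the class comparisons leave them out while their share was above that in Control. When the cells were clustered without the genes that differ between libraries, 94.0% of the NAPH cells of cluster 3 joined AT2-like cells. Of the NAPH cells of cluster 8, 54.1% joined AT2-like and 43.2% AT1-like cells, while 95.5% of those of cluster 16 stayed unnamed. The genes left out had been chosen with clusters 3 and 8 counted as AT2-like, so their joining was favoured in advance. A cluster held mostly by 1 library can reflect that library rather than a cell state, which no replicate here can settle. Cluster 8, however, had 30 Control cells with several of its top genes near the level of its 292 NAPH cells. Krt8 stood at 929.5 and 1035 CPM, Sprr1a at 383.0 and 490.6 and Areg at 351.6 and 521.1. Hbegf (38.3 and 107.0) and Lrg1 (292.4 and 1575) differed more. Cells of this kind were thus present in both libraries, while the cause of their larger share in NAPH stays open.

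The first pattern weighed is the set of 43 genes in AT2-like cells with at least 100 CPM, outside the reach of free RNA, whose whole interval lies beyond a 1.5 times difference. A shift of the whole library would move them alike in other cells. In dendritic-like cells the 9 of these genes that were measured had a median log2 ratio in the AT2 direction of 0.13 (-0.03 to 0.37), against 0.77 in AT2-like cells, and in ciliated-like cells 16 had 0.28 (0.12 to 0.67) against 0.82. Without the free RNA condition, 38 genes were higher, and free RNA could give 2 of them, 5.26% (0.644 to 17.7), which argues against it for the higher genes. The dendritic-like value argues against a shift alike in every cell type, for these 9 genes only. A shift shared by epithelial classes, a response to the injury and a difference between the animals stay open. Some list medians were alike in dendritic-like and AT2-like cells, at 0.37 and 0.38 for cholesterol synthesis and 0.34 and 0.36 for inflammatory mediators. Others were not, such as MHC class I at -0.13 and 0.29. For the lists that moved alike, a shift of the whole library stays open.

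The second pattern is the set of 23 genes with at least 50 CPM in NAPH club-like cells whose whole interval, relative to all genes, lies above 4 times. It includes the alveolar marker Ager, at 795.9 and 1159 CPM in cluster 10 against 956.9 and 1183 in AT2-like cluster 0. Survival, without change, of a state already present in Control would leave no difference within cluster 10 for genes picked from other cells. Cluster 10 held 15 Control and 138 NAPH cells. Within it the 16 genes outside the reach of free RNA had a median log2 ratio of 1.91 (0.83 to 3.03), with 14 higher in NAPH. The median in the whole class was 3.32, so that a larger part of cluster 10 in NAPH may make up the remainder. However, the genes were picked for high levels in the 153 NAPH club-like cells, 138 of which are these same cells. Such a choice favours genes higher in NAPH within the cluster. These values therefore cannot decide on survival without change, which stays open. If doublets with AT2-like cells made the pattern, Sftpc in NAPH club-like cells should exceed 1.5 times its ciliated-like CPM. It was 0.825 times that CPM. Club-like cells were deeper, however, at a median of 17157 UMIs against 8067.5, which lowers the CPM of RNA from another cell. The 153 NAPH club-like cells held 26969 Sftpc UMIs and the 204 ciliated-like cells 22154. That comparison therefore cannot decide on such doublets. In NAPH, Sftpc stood at 9250 CPM in club-like cells, far below 0.2 times its 224829 CPM in AT2-like cells. RNA from AT2-like cells would bring in other genes at no greater proportion. The 16 genes outside the reach of free RNA stood, by that rule, at no less than 0.2 times their AT2-like level. This argues against doublets with AT2-like cells as the source of these 16 genes. For the other 7 genes such doublets stay open. Free RNA could give 7 of the 23 genes, 30.4% (13.2 to 52.9), so for these it stays open, beside a response to the injury.

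The third pattern is the lower level of Scgb1a1 in the ciliated-like cells of the NAPH library. Free RNA alone does not account for the whole of it, since Scgb1a1 in Control ciliated-like cells was 12.0 times its level in dendritic-like cells. This rests on cluster 19, with 91.6% of the Scgb1a1 UMIs of the class, while in cluster 7, at 21697.7 CPM against 12533.9 in dendritic-like cluster 6, free RNA stays open. In Control, 17 cells with doublet scores in the expected share held 77.0% of these UMIs, and without them the Control level was 47697 CPM in place of 151934. The doublet score itself goes up with club cell RNA, so doublets of ciliated-like with club-like cells cannot be told apart from single cells that express both sets of genes.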

How the results depend on the processing

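The alternatives chosen only after seeing the data were the common UMI minimum, doublets at the expected rate in both libraries, unnamed alveolar clusters joined to AT2-like cells, goblet-like joined to club-like cells, clustering without differing genes and lists without members within reach of free RNA. No paired analysis was possible because each group has 1 library. The values below are plain CPM ratios, list medians minus that of all genes, and ratios of shares. Where they differ, the cause was not tested. The ratio of ciliated-like shares was below 1 in each setting. With the stricter filter and the common UMI minimum the cells were clustered and named anew, and fewer than 50 NAPH cells were named club-like. No club-like gene values exist there, and dendritic-like cells gave none with each library clustered on its own.

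Clustered without differing genes, list medians in AT2-like cells were 0.23 for NRF2 targets and 0.56 for transitional epithelial genes, and in club-like cells 1.22 for secretory products and -0.11 for ciliogenesis regulators. The AT2-like share ratio was 1.22 and the goblet-like 0.315. With the common UMI minimum, share ratios were 0.0245 for club-like and 1.26 for goblet-like cells. With doublets at the expected rate in both libraries, ciliated-like ratios were 1.18 for Cyp2f2, 5.27 for Scgb3a2 and 3.88 for Trf, medians 1.68 for secretory products and 0.0402 for xenobiotic metabolism, and the AT2-like share ratio 0.886. With doublets kept, Sftpc in ciliated-like cells stood at 1.08 and the AT2-like share ratio at 0.648.

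With each library clustered on its own, AT2-like medians were 0.0313 for S phase and 0.35 for transitional genes, and share ratios 1.23 for AT2-like, 3.27 for all non-epithelial and 5.48 for dendritic-like cells. With goblet-like cells joined to club-like cells, Adh7 stood at 1.48 and S phase at 1.08. By the highest marker score per cell, AT2-like medians were 0.25 (NRF2 targets), 0.23 (G2 and M phase) and 0.38 (transitional), and club-like medians 0.95 (S phase) and 2.86 (G2 and M phase). Share ratios by this score were 1.12 for AT2-like, 1.70 for basal-like and 1.46 for non-epithelial cells. Without members that free RNA could give, xenobiotic metabolism in AT2-like cells stood at -0.23.

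The looser filter gave an AT2-like share ratio of 1.15, and resolution 2 one of 0.997. Resolution 0.5 gave 1.25 for AT2-like, 0.0232 for club-like, 0.0351 for club-like and goblet-like together, 0.0678 for goblet-like, 0.697 for non-epithelial and 0.431 for macrophage-like cells. The stricter filter gave 0.00780, 0.0243 and 0.0991 for club-like, both and goblet-like cells, and AT2-like medians of 0.22 (interferon) and 0.25 (transitional). By the mean of CPM per cell, Cyp2f2 in ciliated-like cells stood at 1.195 and xenobiotic metabolism at -0.0618.

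Thinned to 2000 UMIs, AT2-like medians were 0.0105 (S phase) and 0.36 (interferon). In ciliated-like cells Cyp2f2 stood at 1.29, xenobiotic metabolism at -0.00523 and G2 and M phase at 0.18. In club-like cells MHC class I stood at -0.15 and heat shock at -0.64. With clusters 3 and 8 joined to AT2-like cells, medians were 0.27 (NRF2 targets), -0.0188 (S phase), 0.27 (G2 and M phase) and 0.69 (transitional), and the share ratio 1.27.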

Other observations

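In this part the genes and lists named were selected, and the clustering without differing genes was added, only after the values were seen. In dendritic-like cells inflammatory mediators had a median log2 ratio 0.34 above all genes (percentile 99.9), with 6 of 16 members at least 1.5 times higher and 1 lower. The interleukin gene Il1b had 10 Control and 79 NAPH UMIs (9.01 times, 4.65 to 19.5) and the chemokine gene Cxcl2 0 and 51, at least 19.4 times higher, while Tnf had 51 and 16 (0.358, 0.190 to 0.637). The medians of immediate early genes (3 of 20 members higher and 5 lower) and of S phase genes (0 of 36 higher and 14 lower) both lay at -0.36 (percentile 0). The class lacks the dividing cells of unnamed cluster 14, 44 in Control and 31 in NAPH, of which 97.7% and 96.8% joined dendritic-like cells when clustered without the differing genes. Interferon response lay at -0.27 (2.42), where Ifitm3 stood at 0.272 (0.185 to 0.392) and Isg15 at 2.17 (1.37 to 3.49). Socs3 stood at 2.51 (1.74 to 3.68) and the transcription factor gene Klf2 at 0.591 (0.495 to 0.703).

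Macrophage-like or monocyte-like cells lay mostly in cluster 13 in Control and in cluster 9 in NAPH, so their ratios, given relative to an all-gene median of -0.14, compare different clusters. Cluster 13 was led by Chil3, Ccl6 and Ear2, and cluster 9 by Mgl2 and the dendritic marker Cd209a. Cluster 9 had 5 macrophage and 2 dendritic markers among its top 50 genes, with 1 of each among the top 10. Cd209a stood there at 822.0 and 876.5 CPM, against 88.6 and 3.37 in dendritic-like cluster 6. The complement genes C1qc (193 times, 1 and 254 UMIs), C1qa (51.7) and C1qb (45.9), all class markers, were higher in NAPH, as was Il1b (27.8, 11.7 to 86.7). Marco (0.0180), a scavenger receptor gene and class marker, Gal (0.0897) and Fabp1 (0.0903) were lower. Cholesterol synthesis lay 1.05 above all genes (percentile 100), with 18 of 19 members higher, among them Sqle (4.62, 2.55 to 9.05), and inflammatory mediators 0.77 above (100), with 11 of 17 higher. G2 and M phase lay at -0.95 (0), with 28 of 42 members lower, and Top2a had 65 and 20 UMIs (0.234). These values leave out the dividing cells of unnamed cluster 21, 10 in Control and 18 in NAPH, with Top2a at 341.1 and 428.5 CPM, all of which joined this class when clustered without the differing genes. When the cells were clustered without the differing genes, the plain CPM ratio of C1qc was 10.8.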
